A study of Oryza sativa Japonica Group with 18 samples.

How the data were processed

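Small RNA-seq, mRNA-seq and whole-genome bisulfite sequencing were done on the shoot base of rice (Oryza sativa, Japonica group) seedlings of 2 genotypes, with 3 samples per genotype and assay. The genotypes were wild type and RNAi plants in which both genes of the largest subunit of RNA polymerase IV, OsNRPD1a and OsNRPD1b, were targeted, and each sample was put in its group from its label. The 6 bisulfite samples were not analysed here. The labels number the replicates but do not say whether they came from separate plants or pools, so the p-values measure only the spread between these samples, which may be technical.

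For each small RNA library the authors deposited a list of distinct sequences of 18 to 28 nt, each with its raw read count. Trimming, the length limits and any removal of structural RNA before those lists were made are not given in the sources used here. For the mRNA the authors deposited 1 table of their own comparison, with no value for any single library. Its signal column is, per the file headers, the DESeq2 mean over libraries of counts divided by size factors. Its log2 fold changes and their standard errors (SE) are the authors' deposited values, and so is its score, the Wald statistic, which equalled the fold change divided by the SE. The p-values and the Benjamini-Hochberg adjusted p-values were also taken as the authors deposited them. Bowtie, TopHat and DESeq2 are named in the submitters' processing notes with no version, and the genome build, the alignment settings and the counting are not given in the sources used here. Reads of near-identical paralogs, of overlapping or antisense genes and of the RNAi transgene itself could have been counted for a gene in ways that the table does not show. The table does not state the direction of its fold changes. It was read as RNAi over wild type, since both targeted genes were then lower in the RNAi plants, and the direction of every mRNA result rests on this reading.

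The small RNA libraries held 18016849, 17718154 and 20272898 reads in wild type and 20174658, 19101699 and 18489087 in the RNAi plants. With that depth, a difference in a length share was limited by the spread between libraries rather than by counting. Reads carried no molecular identifiers, so counting error alone is covered by any count-based limit. No replicate pair was within sampling noise, with chi-square values per 24-nt sequence of 1.74 to 5.64, and each library was counted as 1 sample. Deviations from the group mean of libraries with the same replicate number had correlations of 0.0594, -0.0134 and 0.120 across sequences, so replicate numbers were not used as pairs, and a replicate block was run only as an alternative. Some length shares did follow the replicate number. Replicate 3 had the lowest 19-nt share (4.90% in wild type, 4.65% in RNAi) and the highest 28-nt share (5.48% and 8.32%) of each genotype. A batch shared by replicate number is thus not excluded, and the tests of length shares took no account of it.

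Length shares, ratios and first bases were compared with two-sided exact permutation tests, in which 3 samples against 3 give 10 splits and no p below 0.1. Benjamini-Hochberg adjustment was over 11 lengths. The design planned counts of 24-nt reads in 500-bp windows of the genome, or of each distinct sequence where reads could not be placed. No reference genome was used here, so 24-nt reads were counted per distinct sequence. Of the 5472796 distinct 24-nt sequences, the 56004 with at least 30 reads over the 6 libraries were tested with edgeR 4.0.16 (quasi-likelihood test), with all reads of a library as its size and no TMM scaling. The tested sequences held 40.8% of the 24-nt reads of wild type and 84.8% of those of the RNAi libraries. Listed mature miRNA sequences were matched exactly and summed per family, with the trans-acting siRNA tasiR-ARF counted as a family, and the 24 families with at least 30 reads were tested with edgeR with the listed miRNA reads as library size and TMM scaling. Results passed at an adjusted p under 0.05. Listed miRNAs made up 0.185% to 0.309% of the reads of a library.

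The mRNA results are the authors' deposited fold changes and adjusted p-values. The 16 gene lists were tested with cameraPR of limma 3.58.1 on the deposited Wald statistics, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. A correlation estimated from the samples, fry and a refit of the mRNA data need values per library and could not be run, so a preset correlation of 0.05 was added. The lists were written from general knowledge of rice before the data were examined, as were the other tests named so far, the thresholds and the rule for names. The planned list test was limma's camera on a fit of the libraries, and cameraPR took its place after the table was found to hold no value per library. The rule names both RNAi targets, list members that passed (up to 4 per list, by smallest p), D14, SPL14 and TB1 whatever their p, and the 10 genes with a name that rose and the 10 that fell most among those with a mean of at least 50. It also names the 5 sequences with the smallest p that fell and the 5 that rose, every miRNA family that passed, and miR156. The condition that the groups do not overlap could not be applied to mRNA, and CYP99A3, MAS, WRKY76 and the genes and families given as examples of those that did not pass (RDR2, AGO4A, RCA, CDKB2;1, miR159 and tasiR-ARF) were chosen after their values were seen. A gene name was printed only where a RefSeq table of assembly ASM3414082v1 held the symbol on the chromosome, and in the gene order, that the identifier gives. Of 157 list members 102 met this, and the other 55 were counted but not named, except both RNAi targets and TB1. Micro RNA genes carry their names in the deposited table. Tests of 24-nt reads at tillering loci, of small RNAs by position within the RNAi target genes, and of the relation between small RNA loss near a gene and its mRNA need a genome and were not run.

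The edgeR tests and the list test were tried on simulated data, and the exact permutation tests were not. With 56004 sequences, of which 71, 62 and 67 were changed 2-, 4- and 8-fold, edgeR recovered 8.45%, 54.8% and 76.1% of these, with 3 false calls. Far fewer sequences were changed than were called in the data, so these shares do not give the power of the real test. With 24 miRNA families it recovered 1 of 2, 1 of 1 and 3 of 3 families changed 2-, 4- and 8-fold, with 2 false calls. A single draw of so few families gives no error rate, but false calls among the miRNA families that passed are not excluded. The list test on 25210 genes recovered 100% of shifted lists in 100 draws and called 0.643% of the others. In each draw 2 lists were shifted by 2 SD and the statistics were independent. The share of false calls thus does not cover lists of genes that move together. Alternatives were other library sizes, TMM, DESeq2 1.42.0 (Wald test), other minimum counts, a replicate block, each library left out in turn, other length windows, and for mRNA other filters and a fold threshold. Scripts were run in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and in R 4.3.3.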

Results

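Small RNAs and mRNAs of the rice shoot base, the part of the seedling that bears the axillary buds from which tillers grow, were compared between wild type and RNAi plants in which OsNRPD1a and OsNRPD1b were targeted. These genes encode the largest subunit of RNA polymerase IV, a plant polymerase whose transcripts are made into the 24-nt small interfering RNAs (siRNAs) of RNA-directed DNA methylation. Each genotype had 3 small RNA libraries, of 17718154 to 20272898 reads in wild type and 18489087 to 20174658 reads in the RNAi plants. The mRNA comparison was read from the authors' deposited table of 56377 genes and micro RNA loci, which gives no value per library, so its depth per library is unknown.

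The targeted genes were read first. The authors' deposited table does not state the direction of its fold changes, which was taken from these genes being lower in the RNAi plants, so their fall checks neither the direction nor the labels. In the authors' deposited table, OsNRPD1a (LOC_Os04g48370) fell, with a log2 fold change of -1.64 (SE 0.23, adjusted p = 8.30e-11) at a mean normalised count of 170. OsNRPD1b (LOC_Os09g38268) fell as well, with a log2 fold change of -2.27 (SE 0.36, adjusted p = 2.93e-08) and a mean of 64.1 in the authors' deposited table. As a list, the 2 targets, whose direction was fixed by that reading, passed with limma's cameraPR on the Wald statistics of the authors' deposited table (adjusted p = 3.17e-05; 0 rose, 2 fell, and 2 fell adjusted over the list alone), but not with its rank-based form (adjusted p = 0.0821). The symbols of both genes were not found in the reference table, and reads of the RNAi transgene may have been counted with these genes in the authors' deposited table.

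The first comparison asked how far the loss of polymerase IV lowered 24-nt small RNAs. Reads of 24 nt made up 30.8% ± 2.003 (SD, n = 3) of the wild-type small RNA reads and 12.9% ± 0.372 (SD, n = 3) of those in the RNAi libraries, a 2.39-fold lower share. Reads of 21 nt, the length of most miRNAs, went from 9.26% ± 0.402 to 13.04% ± 0.0898 (SD, n = 3 each), and the ratio of 24-nt to 21-nt reads from 3.34 ± 0.368 to 0.988 ± 0.0294 (SD, n = 3 each). The higher share was not particular to 21 nt. Shares at 20, 22 and 25 to 28 nt were higher as well, by 1.54- to 1.58-fold at 26 to 28 nt against 1.41-fold at 21 nt. The 23-nt share was lower, at 11.9% in wild type and 11.2% in the RNAi libraries, and the 18-nt and 19-nt shares overlapped. By replicate number, the 18-nt share was 3.54%, 3.22% and 2.27% in wild type and lower in each RNAi library, at 2.67%, 2.69% and 1.77%. The variety of 24-nt RNAs differed more than their reads: a wild-type library held 2278804 ± 80480 distinct 24-nt sequences and an RNAi library 348619 ± 35838 (SD, n = 3 each), 6.54-fold fewer. Distinct 23-nt sequences were 5.27-fold fewer. The lower variety was not confined to these lengths. Distinct sequences were 2.63-fold fewer at 18 nt, 2.22-fold at 19 nt and 2.07-fold at 20 nt. They were 2.32-fold fewer at 21 nt, where the read share was higher, 3.12-fold at 22 nt and 2.31-fold at 25 nt. At 26, 27 and 28 nt they were 1.23-, 1.37- and 1.41-fold more numerous in the RNAi libraries. Reads of 24 nt that start with A, the first base preferred by the Argonaute proteins that bind siRNAs, were 49.3% ± 0.958 of 24-nt reads in wild type and 37.4% ± 1.11 in the RNAi libraries (SD, n = 3 each). Among distinct 24-nt sequences the share that start with A went the other way, from 46.8% ± 0.715 to 49.3% ± 1.08 (SD, n = 3 each). In each of these measures except the 18-nt and 19-nt shares, the wild-type and RNAi libraries did not overlap. For the measures without overlap the two-sided exact permutation p was 0.1, the smallest that 3 samples against 3 allow. For the shares of the 24-nt and 21-nt reads it was 0.122 after adjustment over 11 lengths. A share within a library does not give the absolute amount of small RNA.

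**Figure D1:**
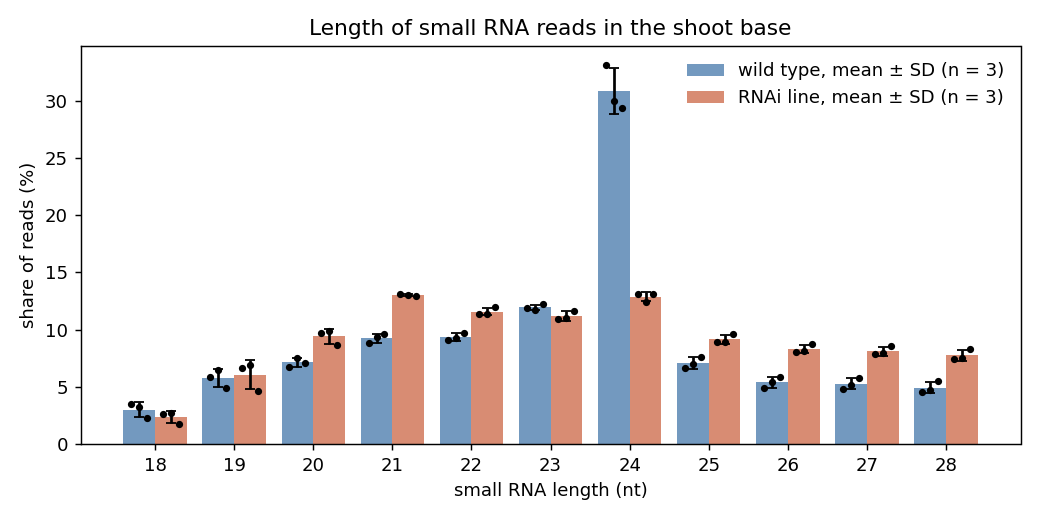
Share of small RNA reads of each length from 18 to 28 nt (horizontal axis, nt; vertical axis, percent of reads of the library) in wild-type and RNAi libraries, with points for single libraries and bars for the mean and SD of 3. The 24-nt share was 30.8% in wild type and 12.9% in the RNAi libraries, and the 21-nt share 9.26% and 13.04%.

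Single 24-nt sequences were then tested one by one. Of 56004 sequences tested with edgeR's quasi-likelihood test, 45076 fell in the RNAi libraries (80.5%), 5386 rose (9.62%) and 5542 did not pass. The fallen sequences had a median log2 fold change of -3.79, or -3.65 with the 6001 that had no read in the RNAi libraries set to a bound of 3 reads. The sequence with the smallest p among those that fell, ATCGAAAATCCGACGCGTAGACGT, went from 68.8 ± 5.07 to 0.169 ± 0.157 reads per 1000000 reads of the library (RPM; SD, n = 3 each), a log2 fold change of -8.58 (SE 0.33, edgeR adjusted p = 1.02e-148). The next 4 were CCGGGACTAAAGATCGCTATCTTT with a log2 fold change of -7.42, GCGACGATCTATAGTCACTCGAGT with -7.68, ATCACGACAACAAATTTTGGACGG with -8.42 and GATGGATCTGTACTATATGAGAGC with -7.77. Among the sequences that rose, TTTGATGTGTAGCTTCTGATCAAA had the smallest p and went from 1.002 ± 1.40 to 381 ± 86.3 RPM (SD, n = 3 each), a log2 fold change of 8.50 (SE 0.27, edgeR adjusted p = 1.52e-216). The other 4 were ACTACTGATGGCTCTGGTGTCGGT with a log2 fold change of 8.42, TGATGTGTAGCTTCTGATCAAAAC with 8.37, TTGATGTGTAGCTTCTGATCAAAA with 8.37 and GATGTGTAGCTTCTGATCAAAACT with 8.90. All 5 belong to a set of 2263 small RNAs of 20 to 24 nt that were nearly confined to the RNAi libraries. The sequences that rose had a median log2 fold change of 1.12. No sequence was placed on the genome, so neighbouring sequences of 1 locus count separately. These counts depend on the scaling and their balance on the minimum count: with TMM, which takes most sequences as unchanged, 15786 fell and 11422 rose, and with a minimum of 100 reads 8284 fell and 3453 rose of 13397.

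**Figure D2:**
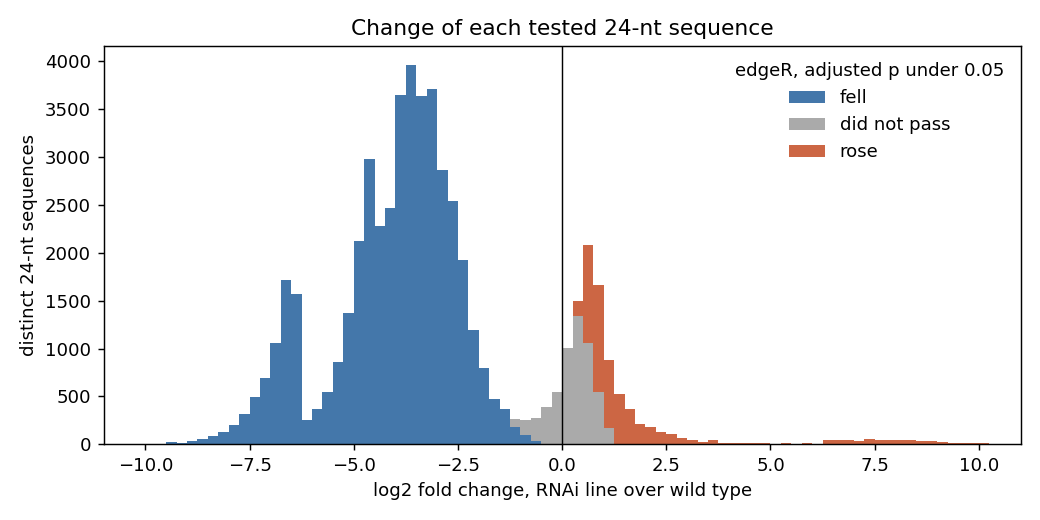
Distribution of edgeR log2 fold changes (RNAi over wild type, horizontal axis) over the 56004 tested 24-nt sequences (vertical axis, number of sequences), split into those that fell, rose or did not pass. Of these, 45076 fell, 5386 rose and 5542 did not pass, and the 6001 fallen sequences without a read in the RNAi libraries have fitted values that are not bounds.

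The miRNA families served as small RNAs that are made without polymerase IV, and the series names tillering, which miR156 influences by repressing SPL transcription factors. miR156 rose in the RNAi libraries, from 1.48% ± 0.168 to 3.06% ± 0.863 of the listed miRNA reads (SD, n = 3 each), with a log2 fold change of 1.28 (SE 0.25, edgeR adjusted p = 1.79e-05). miR390, which directs the cleavage that starts trans-acting siRNAs, rose from 0.229% ± 0.0309 to 0.499% ± 0.0942 (SD, n = 3 each), with a log2 fold change of 1.40 (SE 0.27, edgeR adjusted p = 1.79e-05). miR399, which acts in phosphate starvation, fell with a log2 fold change of -2.95 (SE 0.66, edgeR adjusted p = 1.60e-04), but rested on 38 reads in wild type and 4 in the RNAi libraries. miR394 fell from 1.26% ± 0.376 to 0.579% ± 0.152 (SD, n = 3 each), with a log2 fold change of -0.82 (SE 0.25, edgeR adjusted p = 0.0105). The other 20 of 24 did not pass, among them miR159, with a log2 fold change of 0.61 (edgeR adjusted p = 0.0557). The trans-acting siRNA tasiR-ARF, which was counted as a family, did not pass either. It was lower, with a log2 fold change of -0.95 (edgeR adjusted p = 0.0954), from 53 reads in wild type and 23 in the RNAi libraries. The median log2 fold change of the 24 families was 0.20 with TMM and -0.08 without it, and it was not subtracted from these values. Without TMM the log2 fold changes of miR156, miR390, miR399 and miR394 were 1.04, 1.12, -3.23 and -1.11, so all 4 families kept their direction. Without RNAi replicate 3, miR394 did not pass (log2 fold change -0.62, edgeR adjusted p = 0.180), and without RNAi replicate 1 the log2 fold changes of miR156, miR399 and miR394 were 0.71, -4.38 and -1.31.

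**Figure D3:**
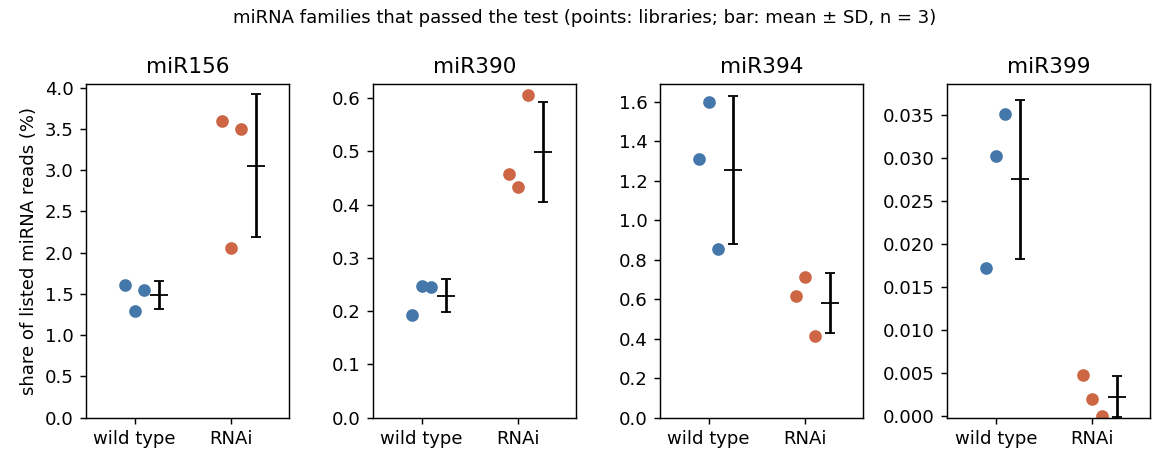
Share of the listed miRNA reads (vertical axes, percent) of miR156, miR390, miR394 and miR399 in each wild-type and RNAi library, with points for libraries and bars for the mean and SD of 3. The mean of miR156 was 1.48% in wild type and 3.06% in the RNAi libraries, and that of miR394 1.26% and 0.579%.

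Micro RNA genes were also read in the mRNA data. MIR156d and MIR156j, precursor genes of miR156, rose in the authors' deposited table, with log2 fold changes of 0.77 (SE 0.18, adjusted p = 6.13e-04) and 0.64 (SE 0.19, adjusted p = 0.00902). MIR156h rose with a log2 fold change of 1.74 (SE 0.61, adjusted p = 0.0382) in the authors' deposited table, and all 5 MIR156 genes tested there were above 0. Of 258 micro RNA genes tested in the authors' deposited table, 14 rose, 7 fell and the others did not pass. Those with the largest log2 fold changes at a mean of at least 50 in the authors' deposited table were MIR1428e at 2.64, MIR1428d at 1.92 and MIR7693 at 1.06 among the risen. The fallen ones by the same rule were MIR5828 at -1.65, MIR3981 at -1.08, MIR2869 at -1.05 and MIR2925 at -1.05 in the authors' deposited table.

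The mRNA comparison asked which genes of the shoot base differed between RNAi plants and wild type. The authors' deposited table tested 25210 genes, of which 1495 rose and 1594 fell, 12.3% of those tested. With a log2 fold change of at least 1 in size as a further condition, 722 rose and 597 fell in the authors' deposited table. The largest changes in the authors' deposited table at a mean of at least 50 were of genes without a checked name, LOC_Os07g05850 and LOC_Os07g05840 with log2 fold changes of 10.85 and 9.37, and LOC_Os01g63930 and LOC_Os02g39330 with -3.61 and -3.46. To reach 10 checked or file-given names in each direction, 282 genes that rose and 601 that fell in the authors' deposited table were passed over as unnamed.

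The list of pathogenesis-related and phytoalexin genes had the highest median of the 16 lists in the authors' deposited table, a log2 fold change of 3.95. KSL4 (LOC_Os04g10060) and CPS4 (LOC_Os04g09900), diterpene cyclases of momilactone synthesis, rose with log2 fold changes of 7.53 (SE 0.76, adjusted p = 2.04e-20) and 7.12 (SE 0.63, adjusted p = 5.77e-27) in the authors' deposited table. CYP99A2 and CYP99A3, cytochrome P450 enzymes of the same pathway, rose by 6.43 and 3.95, and MAS, which makes momilactone A, by 5.52 (SE 1.61, at a mean of 4.11) on the log2 scale of the authors' deposited table. CPS2 and KSL7, cyclases of phytocassane synthesis, rose by 4.11 (SE 0.20, adjusted p = 6.26e-91) and 6.24 (SE 0.68, adjusted p = 1.75e-17), and the pathogenesis-related gene PBZ1 by 1.89 on the log2 scale of the authors' deposited table. WRKY76, a transcription factor that restrains defence, fell with a log2 fold change of -1.82 (SE 0.52, adjusted p = 0.00718) in the authors' deposited table. Of 17 pathogenesis-related and phytoalexin genes in the authors' deposited table, 14 rose, 1 fell and 2 did not pass, and the counts were 14 and 1 adjusted over the list alone (cameraPR adjusted p = 5.79e-43). The cameraPR adjusted p was 6.56e-28 with a preset correlation of 0.05 and 5.47e-07 with the rank-based form. Members such as KSL4 and CPS4 lie close together by identifier and may not move independently, so the size of these p-values depends on the preset correlation.

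Strigolactone, a hormone that represses tiller outgrowth, was represented by its receptor D14 (LOC_Os03g10620). D14 fell in the authors' deposited table with a log2 fold change of -2.81 (SE 0.93, adjusted p = 0.0263) at a mean of 1534, and was 1 of 35 genes with a mean above 500 and an SE above 0.8, of which 34 were lower in the RNAi plants. In the strigolactone and karrikin list, 2 rose, 1 fell and 5 did not pass of 8 tested in the authors' deposited table, the same 2 and 1 adjusted over the list alone, with a median of 0.05, a mean of -0.21 and an upward test that did not pass (cameraPR adjusted p = 0.653). Of the SPL genes that carry a miR156 site, SPL2 fell with a log2 fold change of -0.49 (SE 0.17, adjusted p = 0.0344) in the authors' deposited table. SPL14, which restrains tillering and is itself a miR156 target, had a log2 fold change of -0.59 (SE 0.32, adjusted p = 0.258) in the authors' deposited table. None of the 11 SPL genes with a miR156 site rose, 1 fell and 10 did not pass in the authors' deposited table, with 0 and 1 adjusted over the list alone (cameraPR adjusted p = 0.252). Of the 7 SPL genes without a site, 0 rose and 0 fell in the authors' deposited table, at 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.653).

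Other tillering and meristem genes moved both ways. CKX2, a cytokinin oxidase, rose with a log2 fold change of 2.37 (SE 0.76, adjusted p = 0.0215) at a mean of 25.1 in the authors' deposited table. MADS57, a MADS-box factor linked to tillering, fell with a log2 fold change of -0.87 (SE 0.14, adjusted p = 8.27e-08), and the auxin carrier PIN1b with -0.40 (SE 0.14, adjusted p = 0.0317), in the authors' deposited table. TB1, a repressor of bud outgrowth, failed the name check, with a match only on another chromosome. It had a mean of 1.02 and no adjusted p in the authors' deposited table. The tillering and shoot meristem list had 1 risen, 3 fallen and 5 not passed of 9 tested in the authors' deposited table, with 1 and 3 adjusted over the list alone. Its median was -0.13, its mean 0.24 and its test pointed down without passing in the authors' deposited table (cameraPR adjusted p = 0.353). LOG, which activates cytokinin in meristems, fell with a log2 fold change of -0.53 (SE 0.12, adjusted p = 2.17e-04) and was the only one called of 8 response regulator and cytokinin genes in the authors' deposited table, with 0 risen and 1 fallen adjusted over the list alone (cameraPR adjusted p = 0.653). GID1, the gibberellin receptor, fell with a log2 fold change of -0.56 (SE 0.15, adjusted p = 0.00472) in the authors' deposited table. Of 9 gibberellin genes 0 rose, 2 fell and 7 did not pass in the authors' deposited table, with 0 and 2 adjusted over the list alone (cameraPR adjusted p = 0.252).

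Genes of the silencing pathways themselves mostly did not pass. DRM2, the methyltransferase that siRNAs guide to DNA, rose with a log2 fold change of 0.55 (SE 0.10, adjusted p = 1.88e-06), and DNG701, a DNA glycosylase that removes methylated cytosine, fell with -1.13 (SE 0.21, adjusted p = 2.54e-06), in the authors' deposited table. The other 11 of 13 RNA-directed DNA methylation genes, such as RDR2 with a log2 fold change of -0.14 and AGO4A with -0.03, did not pass in the authors' deposited table, and 1 rose and 1 fell adjusted over the list alone (cameraPR adjusted p = 0.619). AGO18, an Argonaute protein that acts in antiviral defence, rose with a log2 fold change of 1.14 (SE 0.22, adjusted p = 8.35e-06) in the authors' deposited table. In the list of small RNA genes outside that pathway, 2 rose, 0 fell and 10 did not pass in the authors' deposited table, with 2 and 0 adjusted over the list alone (cameraPR adjusted p = 0.189).

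**Figure D4:**
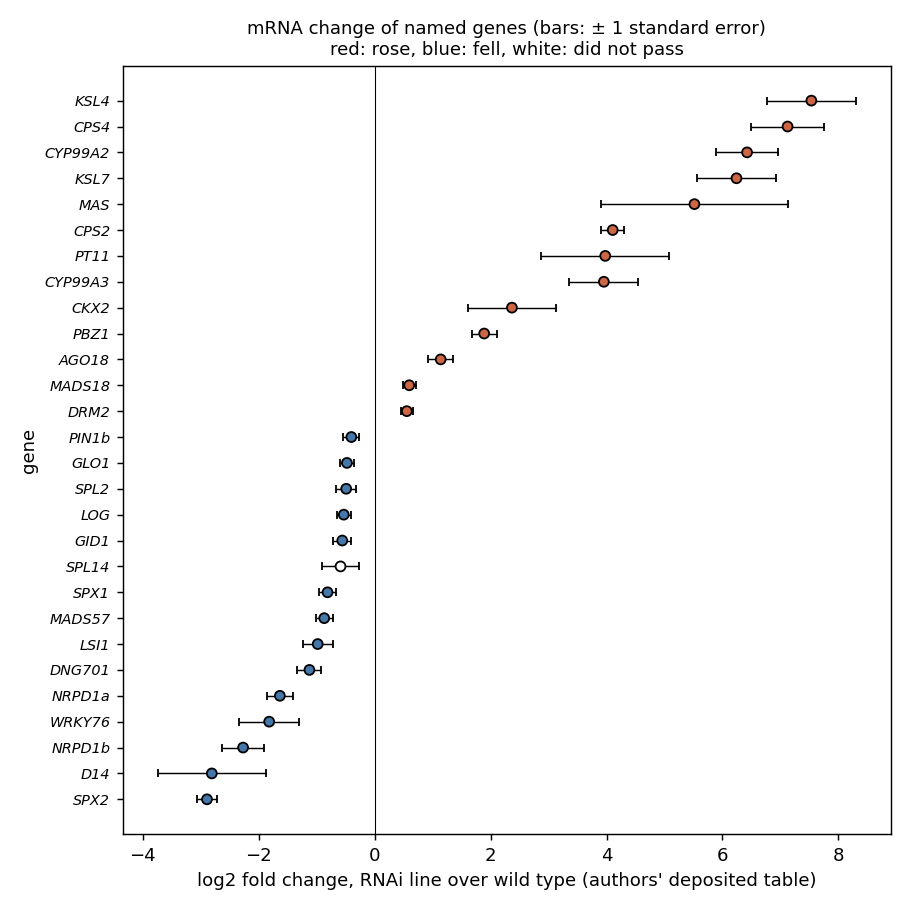
Log2 fold changes (RNAi over wild type, horizontal axis) with their SE for 28 named genes (vertical axis) from the authors' deposited table, coloured by whether they rose, fell or did not pass. KSL4 at 7.53 and SPX2 at -2.89 are the ends of the range, and SPL14 at -0.59 did not pass.

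Markers of other tissues were read to see whether the dissected part differed. GLO1, a glycolate oxidase of photorespiration, fell with a log2 fold change of -0.48 (SE 0.13, adjusted p = 0.00317) in the authors' deposited table, while RCA, the activator of Rubisco, had -0.08 (SE 0.11, adjusted p = 0.723). Of 10 leaf blade markers 0 rose, 4 fell and 6 did not pass in the authors' deposited table, and 0 rose and 7 fell adjusted over the list alone (cameraPR adjusted p = 5.05e-04). With the 4 name-checked members alone, the leaf blade call on the authors' deposited table ended (cameraPR adjusted p = 0.152). All 4 were still lower, with log2 fold changes of -1.31, -0.48, -0.30 and -0.08 in the authors' deposited table, so the call ended with fewer members and not with a change of direction. Among root markers, PT11, a phosphate carrier of roots with mycorrhiza, rose with a log2 fold change of 3.98 (SE 1.10, adjusted p = 0.00498) at a mean of 8.40, and the silicon channel LSI1 fell with -0.98 (SE 0.26, adjusted p = 0.00295), in the authors' deposited table. The root list had 1 risen, 1 fallen and 4 not passed in the authors' deposited table, with 1 and 1 adjusted over the list alone, a median of -0.89, a mean of 0.10 and a downward test (cameraPR adjusted p = 0.653). MADS18, a MADS-box factor of flowering, rose with a log2 fold change of 0.60 (SE 0.11, adjusted p = 3.41e-06) in the authors' deposited table. It was the only one called of 8 inflorescence and flowering markers in the authors' deposited table, with 1 and 0 adjusted over the list alone (cameraPR adjusted p = 0.252).

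SPX2 and SPX1, phosphate sensors that restrain the starvation response, fell with log2 fold changes of -2.89 (SE 0.18, adjusted p = 3.03e-57) and -0.81 (SE 0.15, adjusted p = 1.68e-06) in the authors' deposited table. Of 8 phosphate starvation genes, 2 rose, 2 fell and 4 did not pass in the authors' deposited table, with 2 and 2 adjusted over the list alone (cameraPR adjusted p = 0.252). With the 5 name-checked members alone, the phosphate list of the authors' deposited table passed as lower (cameraPR adjusted p = 1.87e-06). The name check left out both members that rose and kept both that fell, so this pass does not describe the whole list. By ranks the 8 members did not pass (cameraPR adjusted p = 0.823). None of 6 cell division genes (cameraPR adjusted p = 0.618) and none of 5 heat shock genes (cameraPR adjusted p = 0.653) was called in the authors' deposited table, and none was adjusted over the list alone. Among cell division genes, CDKB2;1 had a log2 fold change of -0.72 (SE 0.28, adjusted p = 0.0673) in the authors' deposited table. Over the 16 lists, 3 passed on the authors' deposited table, the targets among them, and the same 3 passed with a preset correlation of 0.05 in place of 0.01, while an estimated correlation could not be had without values per library.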

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

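The set of small RNAs itself, its wild-type limits and the test for the peptide were chosen after the small RNAs had been seen, while the test for carry-over was set before its values were seen.

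A signal outside the planned comparisons was seen in 2263 small RNAs of 20 to 24 nt, chosen for at least 10 reads in each RNAi library and wild-type reads at most 1% of the RNAi reads. They made up 23971 ± 3489 RPM in the RNAi libraries (SD, n = 3), 2.40% of all reads, against 53.8 ± 62.6 in wild type (SD, n = 3). The wild-type libraries held 23.3, 12.2 and 126 RPM in replicates 1, 2 and 3. By length, 43.2% of their RNAi reads were of 21 nt, 30.8% of 22 nt and 20.3% of 24 nt. Overlapping sequences joined into 40 stretches, of which the longest was 185 nt, and the 9 stretches of at least 50 nt held 66.6% of the reads, from both strands. The 486 sequences of 24 nt in this set all rose. Since the set was chosen for the difference, its size is no test of it, and a wild-type limit of 0.1% in place of 1% gives 4366 RPM.

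A candidate explanation is the RNAi transgene, made from a target gene and processed from a hairpin. The peptide DFDGD binds the catalytic metal in the largest subunits of RNA polymerases. It was encoded in 1 of the stretches and in 1 of 10000 shuffles of the same stretches, so the values that this explanation needs are there. The peptide is shared by these polymerases, so it does not tell which of their genes the stretch came from. No stretch was matched to the sequence of OsNRPD1a or OsNRPD1b, so a trigger from either gene was not identified. A second question is the level in wild-type replicate 3, at 0.525% of the RNAi mean. Carry-over of RNAi reads into that library would give counts that follow the RNAi counts: the Spearman correlation across sequences was 0.689 and the length shares were within 1.28 percentage points. The correlation lies between the bounds set for and against carry-over, and above the 0.582 to 0.648 of proportional Poisson draws at that depth. The draws did not apply the wild-type limit by which the sequences were chosen, and that limit itself ties wild-type counts to RNAi counts. Even proportional draws stayed below the bound set for carry-over, so falling short of it says nothing against carry-over. In wild-type replicates 1 and 2, with fewer such reads, the correlations were 0.428 and 0.346. Thus carry-over and a low level in those plants cannot be told apart by this test.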

How the results depend on the processing

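The list test itself, the motifs and the RNAi-confined small RNAs, with their alternatives, were chosen after the data had been seen. Results with miR156 left out of the library size, without genes of high SE, with list members by checked name, and with other correlations, ranks and wild-type limits used alternatives added at that stage as well. Over 248 combinations of a result and an alternative, 228 kept their side of the threshold, or a value within 1 SD or a count within 1.5 times. A reversal was recorded in 0, but for gene lists it was looked for only where the main test had passed. The strigolactone and karrikin list, which had not passed, pointed up in the main test and down with checked members alone. Single mRNA genes kept the log2 fold change of the authors' deposited table in each alternative, so only their side of the threshold was free to differ. The 24-nt share differed by -18.0 points, and by -21.6 with reads of 20 to 25 nt as the denominator, -22.2 with distinct sequences and -20.0 without the 100 most abundant sequences, with a range of -18.7 to -16.8 when each library was left out. The 21-nt share differed by 3.79 points, and by 7.13 with reads of 20 to 25 nt as the denominator. Reads with the Stowaway motif had a log2 ratio of -4.36, and of -3.66 with reads of 20 to 24 nt. Fallen 24-nt sequences were 15786 and risen ones 11422 with TMM, which moves the median log2 fold change from -3.44 to -0.91 by its construction. With at least 100 reads, 8284 fell and 3453 rose of 13397, all called with at least 30 as well, so the balance depends on the minimum count. With each library left out, 44709 to 44950 fell and 4648 to 5095 rose, and a replicate block gave 44970 and 5396. Called mRNA genes in the authors' deposited table went from 3089 to 1319 with a log2 fold change of at least 1. Called miRNA families were 4 to 6 when each library was left out. miR394 did not pass without RNAi replicate 3 (-0.62), and miR528, which had not passed (-0.53), passed in 5 alternatives, with log2 fold changes between -1.18 and -0.72. The cause of the miRNA differences was not tested. Refits of the mRNA data (scaling, DESeq2, pseudocount, block, each library left out), fry, an estimated correlation, 1000-bp windows and placement on the genome were not run. Sequences under 30 reads, which held 59.2% of wild-type 24-nt reads, were too shallow to test singly.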

Other observations

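The motifs, the neighbour test, the splits and the tests of the high-SE genes were chosen after the values had been seen, and the bounds for missing reads and for leaf tissue were changed after a first result, in which leaf tissue was left undecided and missing reads were argued against. The tests of the kept 24-nt sequences were set before their values were seen.

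Small RNAs with the ends of MITEs (miniature inverted-repeat transposable elements) were lower in the RNAi libraries. Reads of 24 nt with CTCCCTCCGT, part of the terminal repeat of Stowaway elements, were at 288 ± 41.0 RPM in wild type and 14.05 ± 2.54 in the RNAi libraries (SD, n = 3 each), 20.5-fold lower (two-sided exact permutation p = 0.1, the smallest possible). In wild type, 0 of 50 shuffled motifs had as many reads (median 4.20, highest 53.2), and reads with the shuffled motifs were together 5.18-fold lower in the RNAi libraries. Reads with GGCCAGTCACAATGG, an end of the mPing element, were at 12.4 ± 1.07 and 0.641 ± 0.0109 RPM (SD, n = 3 each), 19.3-fold lower, and reads with its 50 shuffled motifs were together 59.4-fold lower, from a highest of 5.09 RPM in wild type. Shuffled motifs thus were lower as well, so a lower level was not particular to these ends, and a match of a short motif does not place a read in an element.

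Not all 24-nt RNAs fell: 10442 tested sequences that did not fall and lie outside the RNAi-confined set held 76.9% of the 24-nt reads of the RNAi libraries and 20.3% of those of wild type. Most of these reads were of the 4900 that rose, with 66.3% and 16.6%, while the 5542 that did not pass held 10.6% and 3.69%. A candidate explanation is that the 10442 sequences are fragments of longer RNAs, broken at many lengths. Among wild-type reads with the same first 18 nt, the median share of the 24-nt form was 21.96% for these sequences (quartiles 8.66% and 68.8%) and 84.2% for the fallen ones, where under 25% and over 50% had been set beforehand. They started with A in 38.0%, against 63.2% of the fallen ones. Of these sequences, 0.0192% hold a listed miRNA. So few miRNAs are listed that they could hardly have made up most of 10442 sequences, so this share decides nothing about miRNAs as a source. Whether some of the 10442 sequences are siRNAs left by an incomplete knock-down was not tested.

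Of 7956 genes with a mean above 500 in the authors' deposited table, 35 had an SE above 0.8, and 34 of these, D14 among them, were lower in the RNAi plants (55.1% of the others were). Missing reads in 1 or 2 RNAi libraries stay open: with the other libraries unchanged they could lower a mean to log2 of 1 over 3, -1.58, and in the authors' deposited table the median of the 34 was -1.85, with 25 of them below -1.58. The bound for this, the median SE of a single one of these genes (0.89), is wide for a median, but the genes come from the same libraries and were chosen for being lower, so the test decides nothing. Less leaf blade in the RNAi samples stays open as well. The median of the leaf blade list in the authors' deposited table, -0.54, lay above that of the 34 by more than the SD of its members (0.57). RCA was at -0.08 (SE 0.11) there. That bound was set after a first result, and RCA was picked after its value was seen, so neither decides the question. Moreover, 3 members of that list were at -1.59, -1.59 and -1.31 in the authors' deposited table, 1 of them among the 35. A single wild-type library far above the others stays open: 10 further genes of the authors' deposited table with a fold change and no p were all lower, and without values per library this cannot be told apart from a change in all RNAi libraries.

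Genes called in the authors' deposited table tended to lie side by side by identifier. There were 331 pairs of neighbours called in the same direction in the authors' deposited table, 202 risen and 129 fallen, against a median of 189 and a highest of 224 in 1000 shuffles (permutation p = 0.001, the smallest these can give), and 313 without list members. Overlapping genes and near-identical tandem copies, which can share reads, were not set apart.

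For the edgeR results, the 10 splits of 6 libraries are too few for a share under 0.05. Each of the other splits also mixes the genotypes within its groups, so a difference between genotypes widens the spread within groups. Few calls in those splits were thus set in advance and do not measure how many calls would arise without a difference. The real split called 50462 of the 24-nt sequences and the highest of the others 0 (50597 and 11 at an unadjusted p under 0.05 in edgeR). For miRNA families the real split called 4 and the highest of the others 0 (8 and 2 at an unadjusted p under 0.05 in edgeR).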
